A study of Homo sapiens with 12 samples.

How the data were processed

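Total RNA of 12 cultures was measured on one-colour Agilent expression arrays: neo and SOD2-overexpressing Mn11 cells, both derived from MCF-7, in regular or manganese-supplemented medium, with 3 arrays in each of 4 groups. Per the labels, 500 ng of RNA was labelled with Cy3 for each array. The deposited scanner tables hold fluorescence intensity per spot, made by the authors with Agilent Feature Extraction 12 per the submitters' processing notes and 12.0.0.7 per the file headers. The intensity column used, gProcessedSignal, is deposited as background-subtracted by that program and not yet on a log scale. The submitters' processed values were all identical to that column, so they served as no alternative.

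Each table held 45015 spots, of which 1639 were control spots and 43376 measured 41000 probes. Gene names came from a RefSeq annotation table through the accession of each probe, without versions on either side. In this way 28139 probes matched 18691 gene symbols and 12861 did not match, 4153 of these because the files give only the probe's identifier and 352 with a RefSeq mRNA accession absent from the table. Unmatched probes were tested under the name in the files and no gene is named from them. The array annotation refers to the hg19 genome build and the table to a later build, so no coordinates are given. Probes were not aligned again, and genes with near-identical relatives, such as metallothioneins, HLA class II genes and MAGEA2B, were not told apart beyond the annotation.

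Control spots and spots marked as non-uniform or as population outliers were left out, between 77 and 446 spots per array. The log2 of gProcessedSignal was taken, and each array's 75th percentile over its non-control probes was subtracted. Spots of one probe were averaged. A probe was kept when it was well above background on all 3 arrays of at least 1 group, where a probe counted as well above background on an array when at least 0.5 of its spots were. This left 33021 probes. For a gene with several probes, the one with the highest mean over the 12 arrays stood for it. The fit covered 24795 genes, 16039 with a symbol and 8756 without, of which 579 had a missing value (621 values).

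Group means were fitted with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), with empirical Bayes moderation without trend or robust fitting, 8 residual degrees of freedom and 2.19 prior ones. The comparisons were Mn11 against neo in each medium, manganese against regular medium in each line, and the interaction, which is the manganese effect in Mn11 minus that in neo. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and a gene with an adjusted p under 0.05 is said to have changed. The tests are two-sided. Fold values are the absolute log2 difference turned to a ratio, with the direction in words. The number of arrays, 3 per group, limits the precision. The median SE of a log2 difference was 0.139, and 0.197 for the interaction.

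Shifts of 29 gene lists were tested with camera at a preset correlation of 0.01 between genes, which compares a list with all other genes. P-values were adjusted over the lists within a comparison, lists with fewer than 5 tested genes would have been left out, and counts of members adjusted over the list alone stand beside those over all genes. The lists were antioxidant enzymes, manganese and divalent metal transport, iron handling, metallothioneins and zinc efflux, NRF2 targets, hypoxia targets, OXPHOS complex I, OXPHOS complexes II to V, the TCA cycle, glycolysis, mitochondrial chaperones and proteases, ATF4 targets, endoplasmic reticulum chaperones, heat shock proteins, cholesterol synthesis, fatty acid synthesis, estrogen receptor targets, luminal epithelial markers, basal breast markers, mesenchymal transition markers, stem cell markers, matrix and matrix proteases, cell cycle, p53 targets, interferon response, NF-kB targets, immediate early genes, fibroblast markers and leukocyte markers.

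The comparisons, lists, thresholds and the rule for named genes were fixed before the data were examined. The rule names SOD2, the 6 called genes with the largest positive and the 6 with the largest negative difference in each comparison, and up to 3 members with the smallest p of each list described. The largest genes had to carry a symbol, be well above background in both groups and have groups that do not overlap, which chance gives for 10% of genes with 3 arrays against 3. Genes measured on all arrays of one group and on none of the other have only a lower bound, and the 2 with the largest bound in each direction were named.

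The fits were tested on simulated data with 200 changed genes. Of changes of 0.5, 1 and 2 on the log2 scale, 22.4%, 59.7% and 89.4% were recovered for Mn11 against neo in regular medium and 31.3%, 62.7% and 93.9% in manganese medium. For manganese in neo 25.4%, 71.6% and 87.9% were recovered, in Mn11 19.4%, 49.3% and 87.9%, and for the interaction 5.97%, 41.8% and 81.8%. No call had the wrong sign, between 3 and 6 unchanged genes were called, and a list shifted by 0.5 was found with 0 other lists called. The simulated noise was independent between genes, of equal spread on all arrays and without slide effects. These rates hold only under those conditions, not where genes are correlated, slides differ or the lines differ in spread.

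The alternatives tried were quantile normalization, centring on the median, no filter on dim probes, only probes well above background on all 12 arrays, outlier spots kept, every probe by itself, the mean over a gene's probes, a replicate block, leaving out each array, only the 6 arrays of the groups compared, slide as a fixed and as a random block, a robust trended variance, camera with an estimated correlation, and fry. Normexp on the median signal and the median background with an offset of 50, followed by quantile normalization, was added after seeing the data. With slide as a random block the correlation within slides was 0.0284, and 13355 and 13789 genes differed between the lines in regular and manganese medium, 2045 and 1762 changed with manganese in neo and Mn11, and 1952 differed in the interaction. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.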

Results

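Gene expression was measured in MCF-7-derived cells, a human breast cancer line, on 12 one-colour Agilent arrays. The neo line carries the parental label, and the Mn11 line overexpresses SOD2, the mitochondrial superoxide dismutase that holds manganese at its active site. Each line was grown in regular medium or in medium with 25 µM manganese chloride for at least 21 days, and RNA came from confluent cultures in 3 independent preparations per group. The groups are named neo, neo_supp, Mn11 and Mn11_supp, where supp stands for manganese-supplemented medium. The 75th percentile of the signal lay between 1178 and 2255 per array, between 75.2% and 82.3% of spots were well above background, and no spot was saturated. Replicates correlated at 0.992 to 0.994 in neo, 0.994 to 0.997 in neo_supp, 0.990 to 0.993 in Mn11 and 0.985 to 0.993 in Mn11_supp (Pearson's r across genes, which are not independent replicates). The first principal component held 70.9% of the variance and parted the cell lines. Mn11_supp 2 lay apart from the other Mn11_supp arrays on the second and the third component (6.60% and 6.05% of the variance) and had the most outlier spots, 446, and the lowest share of spots well above background. Array neo 1 lay apart from neo 2 and neo 3 on the third component.

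The arrays lay on 3 slides. Slide 1 held neo 1 to 3 and neo_supp 1, slide 2 held neo_supp 2 and 3 with Mn11 1 and 2, and slide 3 held Mn11 3 and Mn11_supp 1 to 3. No slide held both groups of either comparison between the lines. Within a slide, manganese could be compared only on slide 1 for neo and on slide 3 for Mn11, each time with 1 array on one side. Values with slide as a block therefore rest on few arrays. They are given for SOD2, the counts and the called lists, and for some of the other named genes whose call they ended. For manganese in either line the slide-block mean of a called list was within 0.03 of its within-slide mean. That closeness is given by the layout, in which the slide-block effect of manganese is the within-slide difference, and is no separate check. The median over all genes of the difference between Mn11 and neo was -0.15 in regular and -0.17 in manganese medium on the log2 scale, and these differences are relative to that shift. Under quantile normalization, centring on the median and normexp correction it was -0.10, -0.13 and -0.05 in regular medium and -0.09, -0.10 and -0.05 in manganese medium, and no named gene or called list turned direction under them. Differences are between means over 3 arrays, with limma's standard error (SE), and the error of a list's mean is the SD over its genes.

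SOD2 was measured first, as a check of the labels. Its signal relative to each array's 75th percentile was 0.29 ± 0.07 in neo, -0.01 ± 0.06 in neo_supp, 3.46 ± 0.31 in Mn11 and 4.31 ± 0.05 in Mn11_supp (log2, SD, n = 3 each). SOD2 was 9.01-fold higher in Mn11 than in neo in regular medium (log2 difference 3.17 ± 0.13, adjusted p = 4.07e-08) and 19.9-fold higher in manganese medium (log2 difference 4.31 ± 0.13, adjusted p = 6.19e-09). In Mn11 it rose 1.80-fold with manganese (log2 difference 0.85 ± 0.13, adjusted p = 0.00648), with every Mn11_supp array above every Mn11 array. In neo its difference of -0.29 ± 0.13 did not pass the test (adjusted p = 0.201), although it did without Mn11 1, whose array enters only the shared spread (adjusted p = 0.04). The manganese effect on SOD2 was larger in Mn11 than in neo by 1.14 ± 0.19 (adjusted p = 0.00701). With slide as a block the differences between the lines were 3.30 and 4.66 (adjusted p = 7.07e-05 and 1.66e-05). The effect was then -0.29 in neo (adjusted p = 0.459) and 1.08 in Mn11 (adjusted p = 0.0251), and the interaction, at 1.36, was no longer called (adjusted p = 0.0569). The rise in Mn11 was not called either when only the 6 Mn11 arrays were fitted (adjusted p = 0.0915). The gene has 1 probe, and whether it lies in the part carried by the introduced SOD2 sequence is not stated.

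**Figure D1:**
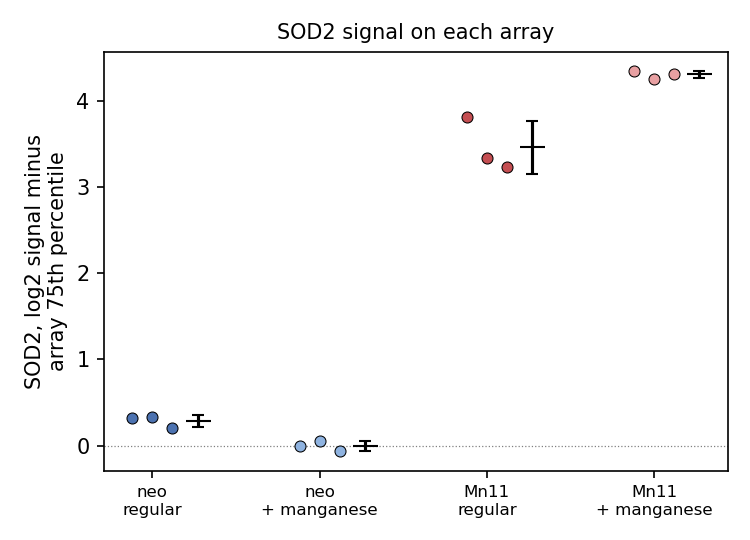
SOD2 signal on each of the 12 arrays (points, log2 minus the array's 75th percentile), with group means and SD (bars, n = 3). The 3 Mn11_supp arrays sit between 4.26 and 4.35, above the Mn11 arrays at 3.23 to 3.81, and all neo and neo_supp arrays lie at 0.33 or below.

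In regular medium the lines were compared without added manganese. In Mn11 35 of 42 cell cycle genes and all 10 tested metallothionein and zinc efflux genes were higher and 12 of 16 mitochondrial chaperones and proteases lower, as lists that did not stay called with an estimated correlation (adjusted p = 0.273 each). The line difference was broad: 13621 of 24795 genes differed, 5641 higher and 7980 lower in Mn11, and 4406 of these by at least 2-fold (2216 higher and 2190 lower). Among genes measured in both lines, BTBD6, an adaptor of cullin ubiquitin ligases, was 624-fold higher in Mn11 (log2 difference 9.28 ± 0.16, adjusted p = 1.99e-10). CDH18, a cadherin, was 205-fold (adjusted p = 3.04e-07) higher and TFPI, an inhibitor of tissue factor in coagulation, 186-fold (adjusted p = 1.76e-08). CIMIP1, ARMCX1 and TMEM25 were 166-fold, 142-fold and 102-fold higher (adjusted p between 2.7e-09 and 4.17e-08). FGFBP2, a binding protein of fibroblast growth factors, was 1188-fold lower (log2 difference -10.21 ± 0.19, adjusted p = 2.66e-10) and INSYN1, an inhibitory synapse protein, 227-fold (adjusted p = 8.1e-09) lower. The potassium channel gene KCNJ8, the muscle filament gene NEB, the blood cell signalling gene VAV1 and MAGEA2B, whose probe is not told apart from its near-identical copies, were 81.3-fold, 65.2-fold, 59.5-fold and 65.0-fold lower (adjusted p between 2.45e-09 and 1.59e-07).

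Another 185 genes were well above background on all Mn11 arrays and on no neo array, and 74 the other way round. Their size is given as a lower bound, the mean of the brighter group against the dimmer group's mean of the higher of the lowest signal well above background and the probe's own. ARHGAP36, a Rho GTPase-activating protein, was at least 576-fold higher in Mn11 (adjusted p = 4.3e-10) and the decoy receptor TNFRSF10C at least 107-fold (adjusted p = 7.95e-09). PSAT1, an enzyme of serine synthesis, was at least 736-fold lower (adjusted p = 1.77e-09) and the membrane glycoprotein GPNMB at least 399-fold (adjusted p = 8.05e-08).

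Of 42 tested cell cycle genes, 35 were higher in Mn11, 1 was lower and 6 did not pass the test (36 and 1 adjusted over the list alone). Their mean log2 difference was 1.03 ± 0.78 (adjusted camera p = 1.01e-13, adjusted p = 0.273 with an estimated correlation, slide-block mean 1.18 with adjusted p = 1.27e-14). CDT1, a licensing factor of DNA replication, was 5.32-fold (adjusted p = 1.81e-08) higher, RRM2, a ribonucleotide reductase subunit, 10.2-fold (adjusted p = 3.71e-08) and PCNA, the replication clamp, 2.79-fold (adjusted p = 1.17e-07). All 10 tested metallothionein and zinc efflux genes were higher (10 adjusted over the list alone; mean log2 1.47 ± 0.40, adjusted camera p = 4.12e-07, adjusted p = 0.273 with an estimated correlation, slide-block mean 1.58 with adjusted p = 6.42e-07). MT1X, MT1H and MT1B, whose near-identical sequences are not told apart here, were 3.06-fold, 3.33-fold and 2.80-fold higher (adjusted p between 1.05e-06 and 1.56e-06). Of 28 matrix and matrix protease genes, 14 were higher, 4 lower and 10 not called (14 and 4 adjusted over the list alone). On average they differed by 0.92 ± 2.02 (adjusted camera p = 0.00682, adjusted p = 0.263 with an estimated correlation, slide-block mean 1.03 with adjusted p = 0.00939). The median was 0.40, and 0.53 with 2 members at their bound and 1 below background in both lines left out. The lysyl oxidase LOXL2 and the urokinase gene PLAU were 7.11-fold (adjusted p = 1.75e-08) and 9.27-fold (adjusted p = 5.92e-07) higher, and the laminin chain LAMB1 12.4-fold (adjusted p = 3.97e-09) lower. Estrogen receptor targets split into 15 higher, 6 lower and 9 not called of 30 (15 and 6 adjusted over the list alone; mean log2 0.35 ± 1.01, adjusted camera p = 0.00682, adjusted p = 0.263 with an estimated correlation, slide-block mean 0.34 with adjusted p = 0.0246). CELSR2 and TFF3 were 3.52-fold (adjusted p = 2.41e-07) and 2.75-fold (adjusted p = 5.63e-07) higher, and the ubiquitin ligase SIAH2 3.72-fold (adjusted p = 1.97e-07) lower.

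Cholesterol synthesis genes were more often higher than lower, 12 against 2 of 23 with 9 not called (13 and 2 adjusted over the list alone). The mean over the list was 0.36 ± 0.57 (adjusted camera p = 0.00743, adjusted p = 0.428 with an estimated correlation, slide-block mean 0.43 with adjusted p = 0.00809). The LDL receptor LDLR and the sterol reductase DHCR24 were 2.97-fold (adjusted p = 3.23e-07) and 3.02-fold (adjusted p = 4.01e-07) higher. Mitochondrial chaperones and proteases were lower in 12 of 16 and higher in 1, with 3 not called (1 and 14 adjusted over the list alone; mean log2 -0.50 ± 0.47, adjusted camera p = 0.00743, adjusted p = 0.273 with an estimated correlation, slide-block mean -0.55 with adjusted p = 0.00477). The matrix protease LONP1 was lower by a log2 difference of -1.58 ± 0.07 (adjusted p = 6.35e-08) and the chaperone HSPA9 was 1.53-fold (adjusted p = 6.22e-05) lower, while the protease YME1L1 was 1.66-fold (adjusted p = 0.00014) higher. Complex I of the respiratory chain had 21 of 37 subunits lower, 5 higher and 11 not called (5 and 22 adjusted over the list alone). Its genes had a mean of -0.34 ± 0.50 (adjusted camera p = 0.0321, adjusted p = 0.703 with an estimated correlation, slide-block mean -0.40 with adjusted p = 0.00477). Its subunits NDUFB10, NDUFA5 and NDUFV3 were 2.69-fold, 2.29-fold and 2.02-fold lower (adjusted p between 2.1e-06 and 7.23e-06). The complex I list was not called under quantile normalization (adjusted p = 0.0773), centring on the median (0.0737) or normexp correction (0.0835), nor without neo 2 (0.0662), neo 3 (0.0552) or Mn11 3 (0.0568). ATF4 targets, genes of the amino acid stress response, were not called here, with 13 higher and 7 lower of 31. Their adjusted p was 0.132, with a median of 0.22 and a mean of -0.08.

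A slide block left 7222 called genes in this comparison, and 6992 genes were called in both fits. On slide 2, where Mn11 could be set only against neo_supp, 96.6% of the 13621 genes differed in the same direction. The Mn11 arrays there also made these calls, so this is no separate check. All 37 genes named for this comparison stayed called with slide as a block.

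In manganese medium the lines were compared with manganese supplied to both. Of the tested genes, 41 of 42 cell cycle, 9 of 10 metallothionein and zinc efflux and 15 of 23 cholesterol synthesis genes were higher in Mn11, and 24 of 31 ATF4 targets were lower. None of these lists stayed called with an estimated correlation (adjusted p = 0.246, 0.513, 0.246 and 0.571). In all, 14153 of 24795 genes differed, 5454 higher and 8699 lower in Mn11_supp than in neo_supp, and 4991 by at least 2-fold (1940 higher and 3051 lower). BTBD6 was 546-fold higher (log2 difference 9.09 ± 0.16, adjusted p = 1.86e-10), CDH18 337-fold (adjusted p = 1.9e-07) and the lysosomal cathepsin gene CTSF 191-fold (adjusted p = 1.94e-09). ARHGAP36, TMEM25 and TFPI were 151-fold, 115-fold and 106-fold higher (adjusted p between 4.01e-09 and 4.26e-08). FGFBP2 was 865-fold lower (log2 difference -9.76 ± 0.19, adjusted p = 3.08e-10). INSYN1, the cytokine gene IL24, VAV1, the phosphodiesterase gene PDE8B and the homeobox gene HOXB9 were 78.9-fold, 66.3-fold, 64.9-fold, 61.7-fold and 57.0-fold lower (adjusted p between 1.37e-09 and 6.95e-07). Among 122 genes seen in Mn11_supp but not in neo_supp, BTG3, an antiproliferative gene, and SDR42E1 were at least 351-fold and 148-fold higher (adjusted p = 9.62e-07 and 4.92e-07). Among 194 seen in neo_supp but not in Mn11_supp, PSAT1 and the cancer-testis antigen gene PRAME were at least 877-fold and 418-fold lower in Mn11_supp (adjusted p = 1.22e-09 and 2.43e-08).

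Cell cycle genes were higher in 41 of 42 and lower in 1 (41 and 1 adjusted over the list alone; mean log2 1.30 ± 0.48, adjusted camera p = 1.83e-21, adjusted p = 0.246 with an estimated correlation, slide-block mean 1.48 with adjusted p = 5.6e-24). The mitotic kinase CDK1, PCNA and the mitotic kinesin KIF23 were 3.99-fold (adjusted p = 2.86e-08), 3.03-fold (adjusted p = 8.15e-08) and 2.94-fold (adjusted p = 2.49e-07) higher. Metallothionein and zinc efflux genes were higher in 9 of 10, with 1 not called (9 and 0 adjusted over the list alone; mean log2 1.06 ± 0.47, adjusted camera p = 7.95e-06, adjusted p = 0.513 with an estimated correlation, slide-block mean 1.29 with adjusted p = 3.75e-06), among them MT1F and MT1X at 4.17-fold (adjusted p = 2.1e-06) and 2.31-fold (adjusted p = 7.95e-06). Cholesterol synthesis genes were higher in 15 of 23 and lower in 1, with 7 not called (16 and 1 adjusted over the list alone). A mean of 0.61 ± 0.62 was found (adjusted camera p = 7.95e-06, adjusted p = 0.246 with an estimated correlation, slide-block mean 0.74 with adjusted p = 1.33e-06). LDLR, DHCR24 and HSD17B7 were 3.15-fold (adjusted p = 2.54e-07), 2.59-fold (adjusted p = 1.16e-06) and 2.03-fold (adjusted p = 2.47e-06) higher. Endoplasmic reticulum chaperones were higher in 10 of 21 and lower in 1, with 10 not called (10 and 1 adjusted over the list alone; mean log2 0.29 ± 0.41, adjusted camera p = 0.0111, adjusted p = 0.513 with an estimated correlation, slide-block mean 0.34 with adjusted p = 0.0213). DNAJC3 and DNAJB11, chaperone partners of the HSP70 family, were 2.71-fold (adjusted p = 9.53e-06) and 1.75-fold (adjusted p = 9.8e-06) higher. Of 31 ATF4 targets, 24 were lower in Mn11_supp, 2 higher and 5 not called (2 and 24 adjusted over the list alone). The list mean was -1.35 ± 2.18 (adjusted camera p = 2.52e-05, adjusted p = 0.571 with an estimated correlation, slide-block mean -1.43 with adjusted p = 3.76e-07). The median was -0.94, and with PSAT1 at its bound the mean of that list was -1.30. SLC7A5 and SLC3A2, the chains of a large neutral amino acid transporter, were 9.79-fold (adjusted p = 4.63e-09) and 5.08-fold (adjusted p = 5.65e-08) lower.

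In a fit with slide as a block 6695 genes were called, 6441 of them in both fits, and all 30 genes named for this comparison stayed called. On slide 2, 96.7% of the 14153 genes differed in the same direction between Mn11 and neo_supp, whose arrays there also made the calls. The calls of the comparisons in regular and manganese medium, which share no array, overlapped in 9953 genes with the same direction. Of these, 4084 were higher (1241 expected of independent lists) and 5869 lower (2800 expected), and another 208 were called in opposite directions. The slide-block calls overlapped in 4600 genes. The log2 differences correlated across genes at r = 0.856 (Spearman's rho 0.749).

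Manganese in neo gives the effect of supplementation without SOD2 overexpression. Of the interferon-response genes 15 of 35 rose, of the immediate early genes 8 of 21 and of the matrix genes 8 of 28, and 3 of 26 targets of p53 fell. With an estimated correlation the immediate early and matrix lists stayed called (adjusted p = 0.046 each), and the interferon and p53 lists did not (0.192 and 0.385). In all 2190 of 24795 genes changed, 1245 up and 945 down, and 247 by at least 2-fold (207 up and 40 down). Under centring on the median 48.8% of 1304 calls were up, so the majority of rises among all calls depends on the scaling. CYP1A1, a cytochrome P450 of xenobiotic metabolism, rose 12.1-fold (log2 difference 3.59 ± 0.29, adjusted p = 0.000404) and its relative CYP1B1 6.25-fold (log2 difference 2.64 ± 0.23, adjusted p = 0.000409). TNFRSF11B, the decoy receptor osteoprotegerin, rose 9.20-fold (adjusted p = 2.03e-06), FST, the activin antagonist follistatin, 5.10-fold (adjusted p = 2.03e-06) and GBP1, an interferon-inducible GTPase, 5.14-fold (adjusted p = 0.000409). The glucuronosyltransferase gene UGT1A6, whose exons are shared with other UGT1A genes, rose 6.20-fold (adjusted p = 0.00204). FOLH1, a folate hydrolase, fell 5.71-fold (adjusted p = 0.000409) and KCNJ8 5.41-fold (adjusted p = 0.000868). KRT24, ANKRD45, the chaperone gene CLGN and GLYATL1 fell 3.12-fold, 3.05-fold, 3.02-fold and 2.92-fold (adjusted p between 0.0036 and 0.0373). Among 9 genes seen in neo_supp but not in neo, ST8SIA1 and ARHGAP36 rose at least 2.90-fold and 2.84-fold (adjusted p = 0.00655 and 0.000404).

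Of the 47 genes named and called for manganese in neo, 31 were no longer called with slide as a block, a fit that rests on neo_supp 1 against the 3 neo arrays. They include UGT1A6 (adjusted p = 0.073), KRT24 (0.221), ANKRD45 (0.0719), CLGN (0.0875), GLYATL1 (0.167) and ST8SIA1 (0.11). Leaving out neo 2, neo 3, neo_supp 2 or neo_supp 3 ended the call of KRT24 (adjusted p = 0.0666, 0.0618, 0.0743 and 0.0578). The call of GLYATL1 ended without any one of the 6 arrays of the comparison (adjusted p between 0.072 and 0.113) and without Mn11_supp 3 (0.0503) or with dim probes kept (0.0596). ST8SIA1 was not called under normexp correction (0.0681).

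Of 35 tested interferon-response genes, 15 rose, none fell and 20 did not pass the test (25 and 0 adjusted over the list alone; mean log2 0.54 ± 0.40, adjusted camera p = 2.46e-14, adjusted p = 0.192 with an estimated correlation, slide-block mean 0.46 with adjusted p = 2.12e-08). The antiviral genes OAS3, RSAD2 and IFITM1 rose 1.83-fold (adjusted p = 0.000868), 2.21-fold (adjusted p = 0.00426) and 1.63-fold (adjusted p = 0.00507). Immediate early genes rose in 8 of 21 with none down (11 and 0 adjusted over the list alone). As a list they differed by 0.50 ± 0.51 (adjusted camera p = 2.64e-08, adjusted p = 0.046 with an estimated correlation, slide-block mean 0.49 with adjusted p = 1.39e-06). The transcription factor genes KLF6 and ATF3 rose 2.63-fold (adjusted p = 0.000183) and 2.18-fold (adjusted p = 0.000933), and ZFP36, an mRNA-decay factor, 1.55-fold (adjusted p = 0.00123). Matrix and matrix protease genes rose in 8 of 28 with none down (12 and 0 adjusted over the list alone; mean log2 0.46 ± 0.50, adjusted camera p = 8.35e-06, adjusted p = 0.046 with an estimated correlation, slide-block mean 0.50 with adjusted p = 0.000121). LOXL2, the plasminogen activator gene PLAT and the collagen gene COL18A1 rose 2.31-fold (adjusted p = 0.000409), 2.83-fold (adjusted p = 0.000992) and 1.53-fold (adjusted p = 0.00344), although PLAT was not called under normexp correction (adjusted p = 0.162). Estrogen receptor targets rose in 9 of 30 with none down (10 and 1 adjusted over the list alone; mean log2 0.30 ± 0.46, adjusted camera p = 0.000162, adjusted p = 0.0599 with an estimated correlation, slide-block mean 0.27 with adjusted p = 0.00321), among them PDZK1 and EGR3 at 2.49-fold (adjusted p = 0.000717) and 1.99-fold (adjusted p = 0.00126). Basal breast markers rose in 6 of 16 with none down (6 and 0 adjusted over the list alone; mean log2 0.39 ± 0.55, adjusted camera p = 0.000691, adjusted p = 0.112 with an estimated correlation, slide-block mean 0.38 with adjusted p = 0.0106), including the annexin ANXA1 at 2.49-fold (adjusted p = 0.00162) and the growth factor receptor EGFR at 1.56-fold (adjusted p = 0.00285), the latter not called under normexp correction (0.343). Targets of NF-kB rose in 5 of 24 with none down (6 and 0 adjusted over the list alone). Their mean log2 difference was 0.28 ± 0.45 (adjusted camera p = 0.00943, adjusted p = 0.251 with an estimated correlation, slide-block mean 0.28 with adjusted p = 0.0602). Of these, RELB and CXCL10 rose 1.64-fold (adjusted p = 0.00507) and 2.82-fold (adjusted p = 0.00798), and the list was not called with dim probes kept (0.0804).

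ATF4 targets rose in neo, with 10 of 31 up, 1 down and 20 not called (16 and 1 adjusted over the list alone; mean log2 0.35 ± 0.43, adjusted camera p = 8.35e-06, adjusted p = 0.385 with an estimated correlation, slide-block mean 0.19 with adjusted p = 0.107). STC2, a secreted glycoprotein, and the lipoprotein receptor VLDLR rose 2.54-fold (adjusted p = 0.000973) and 1.68-fold (adjusted p = 0.00143). NRF2 targets rose in 6 of 29 with none down (11 and 0 adjusted over the list alone; mean log2 0.35 ± 0.57, adjusted camera p = 0.00011, adjusted p = 0.385 with an estimated correlation, slide-block mean 0.31 with adjusted p = 0.0215), among them the efflux pump ABCC1 at 1.38-fold (adjusted p = 0.00443) and the pentose phosphate enzyme G6PD at 1.57-fold (adjusted p = 0.00704). Fatty acid synthesis genes rose in 3 of 15 (5 and 0 adjusted over the list alone; mean log2 0.25 ± 0.29, adjusted camera p = 0.00411, adjusted p = 0.112 with an estimated correlation, slide-block mean 0.19 with adjusted p = 0.168), and the acyl-CoA synthetase gene ACSL3 rose 1.39-fold (adjusted p = 0.0118), a call that ended without neo_supp 2 (0.0522). Cholesterol synthesis genes rose in 4 of 23 (5 and 0 adjusted over the list alone; mean log2 0.15 ± 0.25, adjusted camera p = 0.02, adjusted p = 0.385 with an estimated correlation, slide-block mean 0.18 with adjusted p = 0.0465), led by NSDHL at 1.67-fold (adjusted p = 0.00313). That list was not called without neo 1 (adjusted p = 0.117) or with the mean of all probes of a gene (0.0527). Targets of p53 fell in 3 of 26 with none up (0 and 11 adjusted over the list alone). On average they differed by -0.25 ± 0.24 (adjusted camera p = 0.000151, adjusted p = 0.385 with an estimated correlation, slide-block mean -0.33 with adjusted p = 1.65e-06). BAX, a promoter of apoptosis, fell 1.39-fold (adjusted p = 0.0132), a call that ended without neo 2 (0.0582), neo 3 (0.0568) or neo_supp 2 (0.0602) and with the mean of all probes (0.0759).

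Subunits of complex I fell in 3 of 37 and rose in 1 (1 and 10 adjusted over the list alone; mean log2 -0.15 ± 0.19, adjusted camera p = 0.000197, adjusted p = 0.385 with an estimated correlation, slide-block mean -0.22 with adjusted p = 8.37e-07). NDUFS2 and NDUFC1 fell 1.38-fold (adjusted p = 0.0129) and 1.35-fold (adjusted p = 0.0188), calls that ended without neo 2 (0.0521 and 0.0803) and without neo_supp 2 (0.0595 and 0.0662), the latter gene's also without neo_supp 3 (0.0578). Subunits of complexes II to V shifted down as a list with none of 38 called (0 and 0 adjusted over the list alone). The mean over the list was -0.11 ± 0.14 (adjusted camera p = 0.00701, adjusted p = 0.466 with an estimated correlation, slide-block mean -0.15 with adjusted p = 0.000126). That shift was not called under quantile normalization (0.167), normexp correction (0.314) or fry (0.0894), nor without neo 2 (0.0597) or neo_supp 1 (0.103). Cell cycle genes were not called as a list, with 9 up and 11 down of 42 (13 and 15 adjusted over the list alone). Their adjusted p was 0.621, with a median of -0.03 and a mean of 0.02.

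For manganese in neo 150 genes were called with slide as a block, 92 of them by at least 2-fold, and 134 were called in both fits. Leaving out single arrays gave 987 genes without neo 2, 978 without neo 3, 922 without neo_supp 2 and 1127 without neo_supp 3, and centring on the median gave 1304.

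Manganese in Mn11 shows its effect where SOD2 is overexpressed. Of the ATF4 targets 24 of 31 fell, while 13 of 23 cholesterol synthesis, 3 of 15 fatty acid synthesis and 10 of 42 cell cycle genes rose. With an estimated correlation the lists of cholesterol and fatty acid synthesis stayed called (adjusted p = 0.0399 each), and those of ATF4 targets and the cell cycle did not (0.104 and 0.2). In all 1857 of 24795 genes changed, 789 up and 1068 down, and 304 by at least 2-fold (98 up and 206 down). NUPR1, a stress-induced regulator of transcription, fell 10.0-fold (log2 difference -3.33 ± 0.29, adjusted p = 0.000392). ALDH1L2, a mitochondrial folate enzyme, fell 5.69-fold (adjusted p = 0.00144), BCAT1, a branched-chain aminotransferase, 4.56-fold (adjusted p = 0.00591) and the amino acid transporter SLC43A1 3.99-fold (adjusted p = 9e-05). VLDLR-AS1, an RNA antisense to VLDLR, and the placental gene PLAC1 fell 4.07-fold (adjusted p = 9e-05) and 3.76-fold (adjusted p = 0.00246). MUC1, a transmembrane mucin of luminal epithelium, rose 4.45-fold (log2 difference 2.15 ± 0.15, adjusted p = 0.000133). The MHC class II genes HLA-DRA and HLA-DRB5, the latter with near-identical relatives, rose 3.88-fold (adjusted p = 0.000293) and 4.01-fold (adjusted p = 0.0013). RGS16, a regulator of G protein signalling, FAM133A and the neural transcription factor gene ASCL1 rose 3.76-fold, 4.68-fold and 3.70-fold (adjusted p = 0.00216, 0.0407 and 0.0355). TARP, which shares sequence with a T-cell receptor gene, and MDFIC were seen in Mn11_supp but not in Mn11 and rose at least 4.25-fold and 3.12-fold (adjusted p = 0.00446 and 0.00174). BEST1 and SLC7A7 were seen in Mn11 but not in Mn11_supp and fell at least 4.05-fold and 3.08-fold (adjusted p = 9e-05 and 0.0272).

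Of the 47 genes named and called for manganese in Mn11, 23 were no longer called with slide as a block, a fit that rests on Mn11_supp against Mn11 3. They include FAM133A (adjusted p = 0.176), ASCL1 (0.165), BCAT1 (0.091), PLAC1 (0.0527) and SLC7A7 (0.0949). FAM133A was also not called under quantile normalization (0.0504), with dim probes kept (0.0642), with a replicate block (0.0525), or without neo 2, neo_supp 2, neo_supp 3, any Mn11 array, Mn11_supp 2 or Mn11_supp 3 (between 0.0503 and 0.126). ASCL1 was not called with dim probes kept (0.0567), nor without neo 2, neo 3, any neo_supp array, Mn11 2, Mn11 3, Mn11_supp 1 or Mn11_supp 2 (between 0.0508 and 0.127). SLC7A7 was not called without Mn11 2 (0.0863), Mn11 3 (0.0641), Mn11_supp 1 (0.0708) or Mn11_supp 3 (0.0743).

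Of 31 ATF4 targets, 24 fell with manganese in Mn11, none rose and 7 did not pass the test (0 and 25 adjusted over the list alone; mean log2 -0.92 ± 0.75, adjusted camera p = 1.39e-21, adjusted p = 0.104 with an estimated correlation, slide-block mean -0.92 with adjusted p = 8.96e-21). ASNS, the asparagine synthetase, and PHGDH, the first enzyme of serine synthesis, fell 3.14-fold (adjusted p = 0.000101) and 3.10-fold (adjusted p = 0.000174). The list's median was -0.84, and -0.85 without PSAT1, which was below background in both groups. Relative to the mean of all 12 arrays, the list lay at -0.90, -0.73 and -0.81 on the Mn11_supp arrays against -0.01, 0.22 and 0.10 on the Mn11 arrays. Its members are drawn in the plot of ATF4 targets by cell line.

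**Figure D2:**
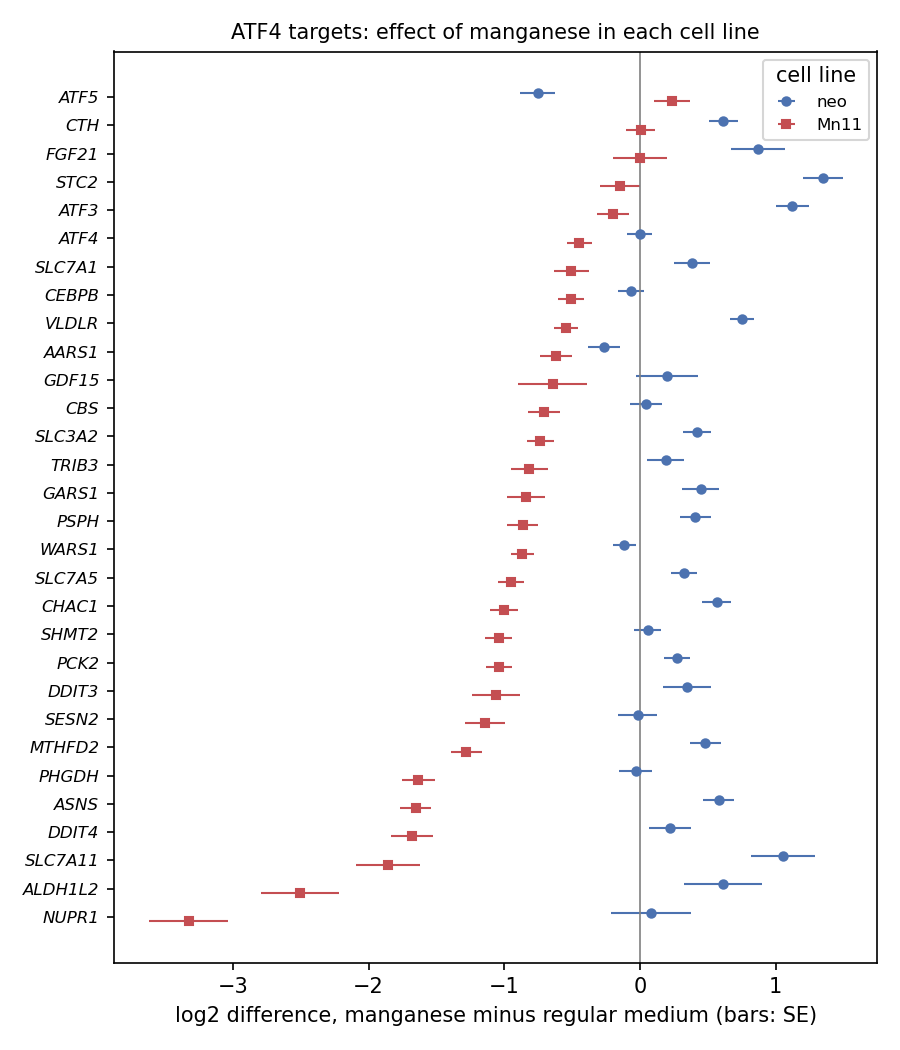
Log2 difference between manganese and regular medium (points, bars SE) for 30 tested ATF4 targets in neo (circles) and Mn11 (squares), PSAT1 left out as below background in Mn11. NUPR1 has the largest fall in Mn11, -3.33, and ASNS lies at 0.58 in neo and -1.65 in Mn11.

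Cholesterol synthesis genes rose in 13 of 23 with none down (15 and 0 adjusted over the list alone). Its genes had a mean of 0.41 ± 0.19 (adjusted camera p = 1.15e-12, adjusted p = 0.0399 with an estimated correlation, slide-block mean 0.48 with adjusted p = 3.29e-11). The lanosterol synthase LSS and the sterol reductase TM7SF2 rose 1.53-fold (adjusted p = 0.00443) and 1.55-fold (adjusted p = 0.00893). HMGCS1, the HMG-CoA synthase, differed by 0.59 ± 0.10 (adjusted p = 0.0107). Fatty acid synthesis genes rose in 3 of 15 with none down (6 and 0 adjusted over the list alone; mean log2 0.38 ± 0.35, adjusted camera p = 2.34e-05, adjusted p = 0.0399 with an estimated correlation, slide-block mean 0.38 with adjusted p = 0.000499), including the fatty acid synthase FASN at 1.61-fold (adjusted p = 0.0151). Cell cycle genes rose in 10 of 42 with 1 down (21 and 1 adjusted over the list alone; mean log2 0.29 ± 0.23, adjusted camera p = 3.4e-11, adjusted p = 0.2 with an estimated correlation, slide-block mean 0.39 with adjusted p = 3.29e-11). CDK1 and PCNA rose 1.45-fold (adjusted p = 0.00441) and 1.34-fold (adjusted p = 0.00981), and CDT1 fell 1.43-fold (adjusted p = 0.00931). Glycolysis genes rose in 4 of 23 with 1 down (10 and 1 adjusted over the list alone; mean log2 0.18 ± 0.34, adjusted camera p = 6.62e-05, adjusted p = 0.198 with an estimated correlation, slide-block mean 0.25 with adjusted p = 0.00018), among them the glucose transporter SLC2A1 at 1.54-fold (adjusted p = 0.0097). Heat shock proteins rose in 1 of 16 (6 and 0 adjusted over the list alone; mean log2 0.26 ± 0.21, adjusted camera p = 0.000331, adjusted p = 0.2 with an estimated correlation, slide-block mean 0.32 with adjusted p = 0.000278), namely HSP90AA1 at 1.39-fold (adjusted p = 0.0264). Complex I subunits rose in 3 of 37 with none down (6 and 0 adjusted over the list alone; mean log2 0.11 ± 0.18, adjusted camera p = 0.00154, adjusted p = 0.507 with an estimated correlation, slide-block mean 0.18 with adjusted p = 0.000631), including NDUFS8 at 1.34-fold (adjusted p = 0.0218). This shift was not called by fry (adjusted p = 0.0821). Subunits of complexes II to V rose in 3 of 38 with none down (3 and 0 adjusted over the list alone; mean log2 0.14 ± 0.17, adjusted camera p = 5.28e-05, adjusted p = 0.452 with an estimated correlation, slide-block mean 0.23 with adjusted p = 1.35e-05), including ATP5F1A at 1.29-fold (adjusted p = 0.0173). The calls of HSP90AA1, NDUFS8 and ATP5F1A ended without Mn11 2 (0.0584, 0.0679 and 0.0695) and without Mn11_supp 2 (0.0733, 0.08 and 0.0563). That of HSP90AA1 also ended without Mn11 1 (0.0511), Mn11 3 (0.0541) or Mn11_supp 1 (0.0684), that of NDUFS8 without Mn11 3 (0.0512) and under centring on the median (0.0762), and that of ATP5F1A without Mn11_supp 3 (0.0534) and under centring on the median (0.0791).

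NRF2 targets rose in 5 of 29 and fell in 2 (10 and 2 adjusted over the list alone). A mean of 0.17 ± 0.56 was found (adjusted camera p = 0.000629, adjusted p = 0.497 with an estimated correlation, slide-block mean 0.14 with adjusted p = 0.0213). The cystine transporter SLC7A11 fell 3.62-fold (adjusted p = 0.00241), and the heme oxygenase HMOX1 rose 1.42-fold (adjusted p = 0.0144), a call that ended under centring on the median (0.0602). This list was not called by fry (0.0821). Immediate early genes rose in 8 of 21 with none down (8 and 1 adjusted over the list alone; mean log2 0.32 ± 0.58, adjusted camera p = 0.00151, adjusted p = 0.2 with an estimated correlation, slide-block mean 0.20 with adjusted p = 0.109), among them EGR2 and IER3 at 3.19-fold (adjusted p = 0.000593) and 1.79-fold (adjusted p = 0.00144). Metallothionein and zinc efflux genes shifted down with none of 10 called (0 and 8 adjusted over the list alone; mean log2 -0.33 ± 0.18, adjusted camera p = 0.000947, adjusted p = 0.477 with an estimated correlation, slide-block mean -0.19 with adjusted p = 0.0969). The interferon-response list shifted up with 1 of 35 up, OAS3 at 1.39-fold (adjusted p = 0.0152), and 1 down (1 and 1 adjusted over the list alone). The list mean was 0.13 ± 0.20 (adjusted camera p = 0.011, adjusted p = 0.703 with an estimated correlation, slide-block mean 0.07 with adjusted p = 0.389). Without Mn11 1 its mean was 0.00 (adjusted p = 0.933), and fry did not call it (0.374). Endoplasmic reticulum chaperones shifted up with 1 of 21 up and 1 down (2 and 1 adjusted over the list alone; mean log2 0.09 ± 0.27, adjusted camera p = 0.0403, adjusted p = 0.477 with an estimated correlation, slide-block mean 0.14 with adjusted p = 0.0604). The member that fell was the stress-induced HERPUD1, by 1.84-fold (adjusted p = 0.00222). That list was called under no other scaling or probe filter, nor with the mean of all probes or fry (adjusted p between 0.061 and 0.185), nor without Mn11 1 (0.0879), Mn11 3 (0.0896), Mn11_supp 2 (0.111) or Mn11_supp 3 (0.0684). With an estimated correlation only the cholesterol and fatty acid synthesis lists stayed called.

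For manganese in Mn11 505 genes were called with slide as a block, 364 of them in both fits. When only the 6 Mn11 arrays were fitted 153 were called, 104 of them by at least 2-fold. Most calls for Mn11 thus depend on a spread estimated from both lines, while the 6 neo arrays alone gave 2239 genes for manganese in neo. In that 6-array fit 34 of the 47 named genes were not called, RGS16 (adjusted p = 0.0636), LSS (0.0793), FASN (0.122), CDK1 (0.0785) and SLC2A1 (0.0886) among them. Leaving out single arrays gave 689 genes without Mn11 2, 781 without Mn11_supp 2 and 1080 without Mn11_supp 3. Of at least 2-fold there were 475, 184 and 517 without Mn11 1, Mn11 2 and Mn11 3. Centring on the median gave 1033 genes and keeping dim probes 1234.

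The study crossed line and medium to separate effects tied to SOD2 from those of manganese. The interaction tests whether the manganese effect differs between lines. The manganese effect was lower in Mn11 than in neo for 24 of 31 ATF4 targets, 3 of 35 interferon-response genes and 6 of 28 matrix genes, as lists that did not stay called with an estimated correlation (adjusted p = 0.259, 0.444 and 0.259). In all 2193 of 24795 genes had manganese effects that differed between the lines, 900 with a higher and 1293 with a lower effect in Mn11, and 670 by at least 2-fold (140 and 530). FOLH1 fell 5.71-fold in neo and had the largest positive interaction of the named genes (log2 difference 3.21 ± 0.30, adjusted p = 0.000653). MUC1, which rose in Mn11, differed by 2.05 ± 0.22 (adjusted p = 0.00099). The protease gene KLK8, the fatty acid elongase ELOVL2, DPY19L2 and SPINK4 also had positive interactions of 2.71, 2.31, 2.27 and 1.90 (adjusted p between 0.00278 and 0.019). CAMP, the antimicrobial cathelicidin, had a negative one (log2 difference -3.64 ± 0.36, adjusted p = 0.000736). NUPR1 differed by -3.41 ± 0.42 (adjusted p = 0.00184) and CYP1A1, which rose in neo, by -3.32 ± 0.41 (adjusted p = 0.00186). VLDLR-AS1, SLC7A11 and SLC43A1 differed by -3.05 ± 0.19, -2.91 ± 0.33 and -2.81 ± 0.18 (adjusted p = 0.000126, 0.00139 and 0.000126).

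Of the 36 genes named and called in the interaction, 24 were no longer called with slide as a block, KLK8 (adjusted p = 0.205), ELOVL2 (0.0599), DPY19L2 (0.147), SPINK4 (0.174), NUPR1 (0.0589), CYP1A1 (0.0697) and SLC7A11 (0.0604) among them. KLK8 was not called without neo 2 (0.0501), neo 3 (0.0506) or neo_supp 2 (0.0534), nor SPINK4 without neo_supp 2 (0.0501).

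Of 31 ATF4 targets, 24 had a lower manganese effect in Mn11 than in neo, 1 a higher effect and 6 did not pass the test (1 and 29 adjusted over the list alone). As a list they differed by -1.27 ± 0.85 (adjusted camera p = 1.57e-22, adjusted p = 0.259 with an estimated correlation, slide-block mean -1.11 with adjusted p = 8.88e-18). ASNS, the folate enzyme MTHFD2 and CHAC1, which degrades glutathione, differed by -2.23 ± 0.16, -1.76 ± 0.16 and -1.57 ± 0.15 (adjusted p = 0.000157, 0.000653 and 0.000653). Interferon-response genes had a lower effect in Mn11 in 3 of 35 with none higher (0 and 4 adjusted over the list alone; mean log2 -0.41 ± 0.36, adjusted camera p = 3.18e-05, adjusted p = 0.444 with an estimated correlation, slide-block mean -0.39 with adjusted p = 0.00188), STAT2 among them at -0.68 ± 0.10 (adjusted p = 0.00356). Matrix and matrix protease genes were lower in 6 of 28 with none higher (0 and 9 adjusted over the list alone; mean log2 -0.47 ± 0.84, adjusted camera p = 0.00451, adjusted p = 0.259 with an estimated correlation, slide-block mean -0.42 with adjusted p = 0.0296). LOXL2 and PLAT differed by -2.13 ± 0.15 and -2.26 ± 0.24 (adjusted p = 0.000147 and 0.000863), PLAT not under normexp correction (0.178). Metallothionein and zinc efflux genes shifted down with none of 10 called (0 and 3 adjusted over the list alone). Their mean log2 difference was -0.41 ± 0.17 (adjusted camera p = 0.00269, adjusted p = 0.444 with an estimated correlation, slide-block mean -0.29 with adjusted p = 0.0559).

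Cell cycle genes had a higher effect in Mn11 in 14 of 42 and a lower one in 2 (18 and 3 adjusted over the list alone; mean log2 0.27 ± 0.58, adjusted camera p = 3.18e-05, adjusted p = 0.435 with an estimated correlation, slide-block mean 0.30 with adjusted p = 8.91e-05). The mitotic genes KIF20A and BUB1 differed by 1.57 ± 0.16 and 1.05 ± 0.15 and CDT1 by -1.34 ± 0.13 (adjusted p = 0.000756, 0.00341 and 0.000653). Complex I subunits were higher in 5 of 37 with none lower (9 and 0 adjusted over the list alone; mean log2 0.26 ± 0.25, adjusted camera p = 4.64e-06, adjusted p = 0.435 with an estimated correlation, slide-block mean 0.40 with adjusted p = 3.17e-09), and NDUFB4 differed by 0.64 ± 0.13 (adjusted p = 0.015). Subunits of complexes II to V were higher in 2 of 38 with none lower (9 and 0 adjusted over the list alone). On average they differed by 0.25 ± 0.24 (adjusted camera p = 5.23e-06, adjusted p = 0.435 with an estimated correlation, slide-block mean 0.38 with adjusted p = 1.41e-08). Cholesterol synthesis genes were higher in 2 of 23 and lower in 1 (11 and 1 adjusted over the list alone; mean log2 0.25 ± 0.31, adjusted camera p = 0.000886, adjusted p = 0.435 with an estimated correlation, slide-block mean 0.31 with adjusted p = 0.000439). Endoplasmic reticulum chaperones were higher in 1 of 21 and lower in 1, HERPUD1 at -1.08 ± 0.16 with adjusted p = 0.00391 (5 and 1 adjusted over the list alone). The mean over the list was 0.16 ± 0.37 (adjusted camera p = 0.0288, adjusted p = 0.435 with an estimated correlation, slide-block mean 0.24 with adjusted p = 0.00558). Targets of p53 were higher in 1 of 26 and lower in 1, SESN2 at -1.12 ± 0.20 with adjusted p = 0.0103 (1 and 1 adjusted over the list alone; mean log2 0.15 ± 0.42, adjusted camera p = 0.0289, adjusted p = 0.575 with an estimated correlation, slide-block mean 0.15 with adjusted p = 0.0559). Neither of these lists was called under quantile normalization (0.117 and 0.0963), normexp correction (0.286 and 0.121) or the mean of all probes (0.129 and 0.0911), nor without neo 2 (0.0782 for both), neo_supp 1 (0.0817 and 0.115) or Mn11_supp 2 (0.0581 and 0.0663). The p53 list was also not called without Mn11 1 (0.185) or Mn11_supp 3 (0.0997) or by fry (0.265). Without Mn11 1 its mean was 0.05, against 0.15 with all arrays. No list stayed called with an estimated correlation.

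**Figure D3:**
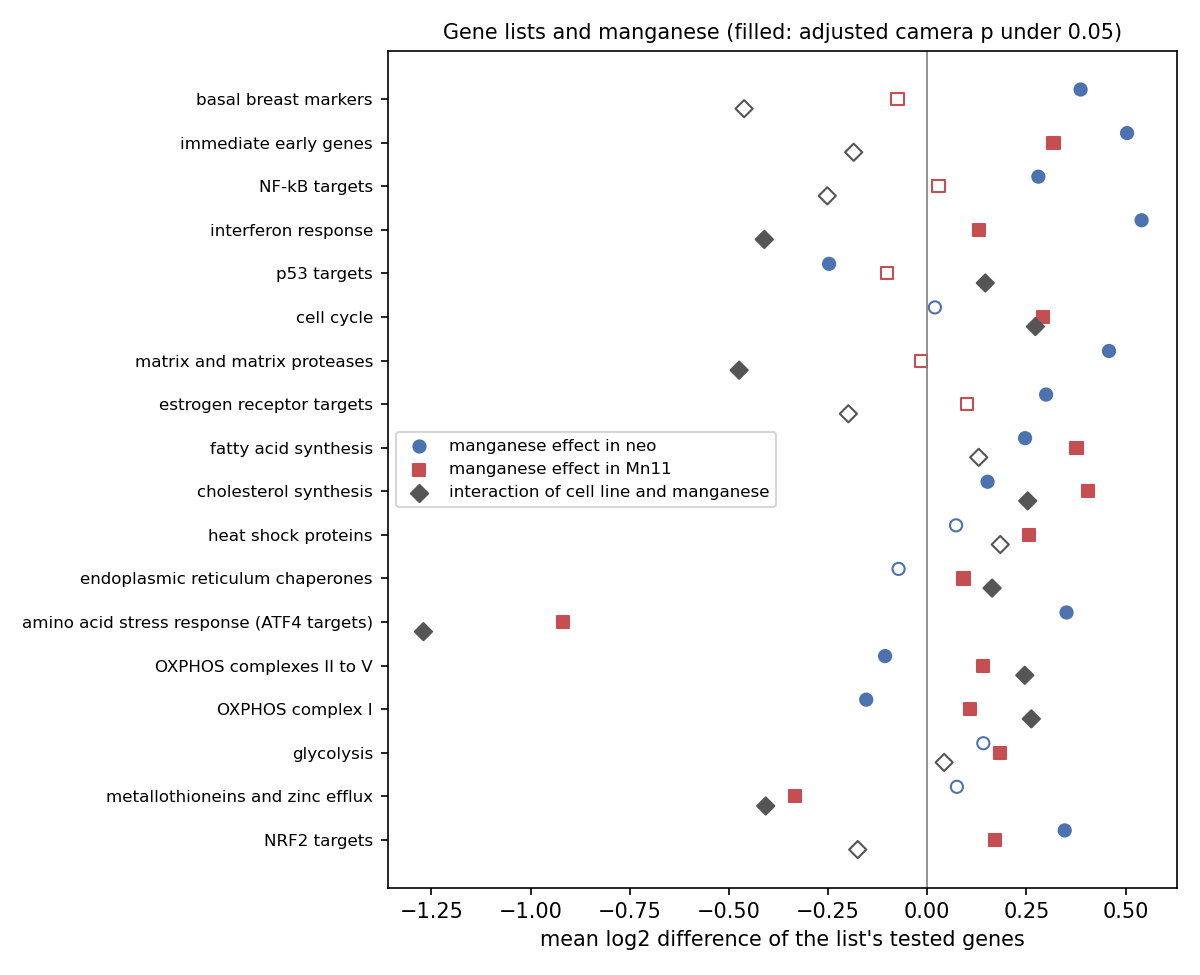
Mean log2 difference of the tested genes of 18 lists for manganese in neo (circles), manganese in Mn11 (squares) and the interaction (diamonds), filled where the adjusted camera p is under 0.05. ATF4 targets lie at 0.35 in neo, -0.92 in Mn11 and -1.27 for the interaction.

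**Figure D4:**
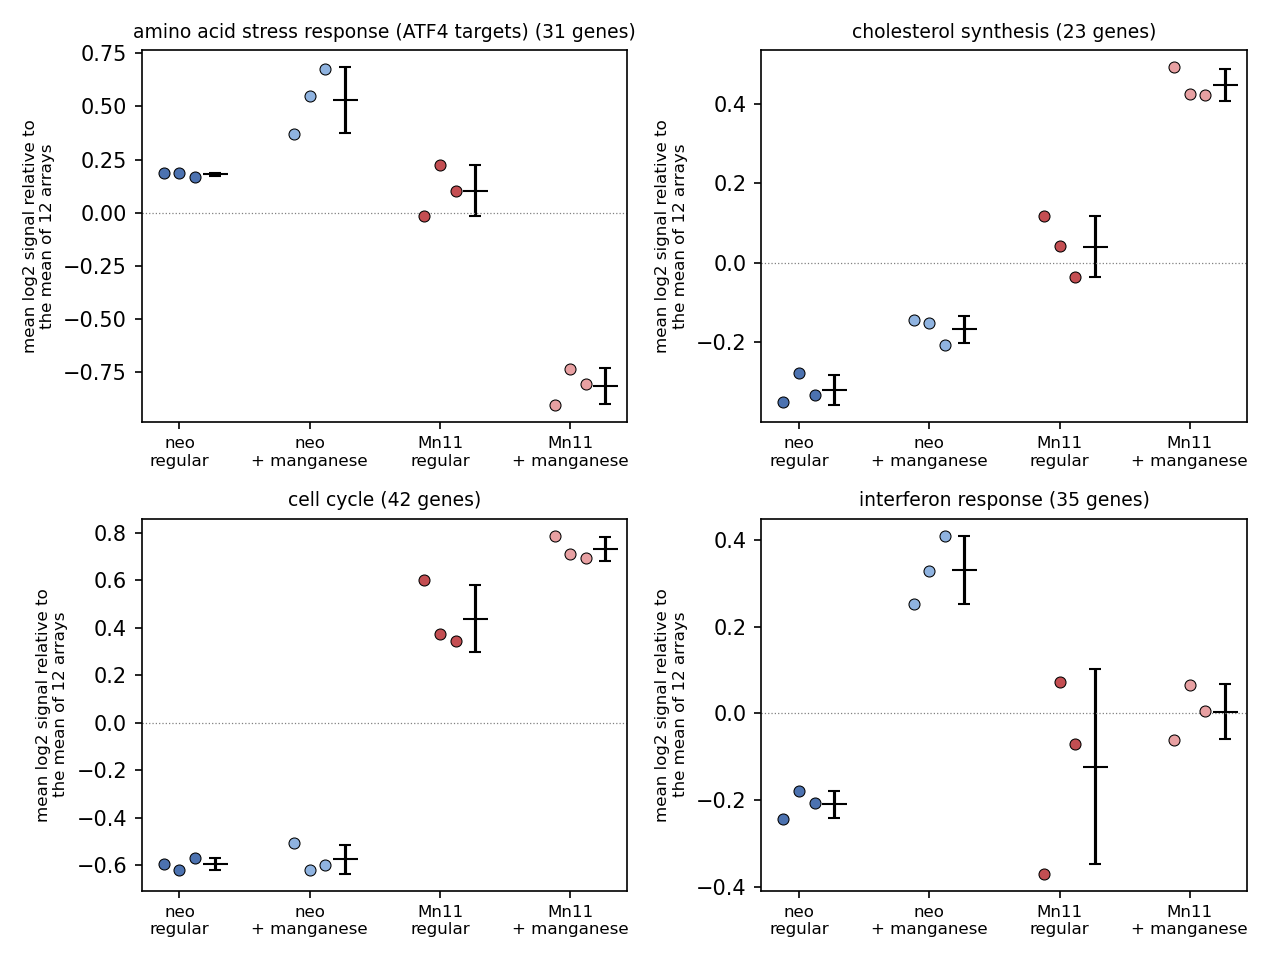
Mean log2 signal of 4 gene lists on each array relative to the mean of the 12 arrays (points), with group means and SD (bars, n = 3). ATF4 targets lie between -0.90 and -0.73 on the Mn11_supp arrays and between -0.01 and 0.68 on all others, and the interferon-response list spreads from -0.37 to 0.07 within Mn11.

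In the interaction 162 genes were called with slide as a block, 156 of them by at least 2-fold. Leaving out single arrays gave 1148 genes without neo 2, 1199 without neo 3, 1087 without neo_supp 2, 1309 without Mn11 2 and 1378 without Mn11_supp 2, and 1180 genes of at least 2-fold without Mn11 3. Centring on the median gave 1228 and keeping dim probes 1451. The manganese effects in the lines share no array. Their calls coincided in 100 genes up in both (39.6 expected of independent lists) and 58 down in both (40.7 expected), while 132 were up in neo and down in Mn11 (53.6 expected) and 54 down in neo and up in Mn11 (30.1 expected). All of these counts lay above the expected ones. The log2 effects correlated across genes at r = -0.06 (Spearman's rho -0.09). The 158 genes called the same way became 11 with slide as a block, 70 under centring on the median, 92 with dim probes kept and 262 with a robust trended variance. They were 78 without neo 2, 73 without neo 3, 77 without neo_supp 2, 77 without neo_supp 3, 252 without Mn11 1, 76 without Mn11 2, 82 without Mn11_supp 2 and 98 without Mn11_supp 3.

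Another 10 lists were called in no comparison, each with adjusted camera p of 0.0731 or more. Of 28 antioxidant enzyme genes, 3 rose and none fell with manganese in neo and 2 rose and 1 fell in Mn11, while 5 were higher and 9 lower in Mn11 than in neo in regular medium (5 and 9 adjusted over the list alone) and 6 and 15 in manganese medium. Manganese and divalent metal transport genes rose in 3 of 16 in neo, and 1 of 16 fell in Mn11, while 2 were higher and 5 lower in Mn11 in regular and 2 and 7 in manganese medium. Of 30 iron handling genes, none changed in neo and 2 rose in Mn11, and 5 were higher and 14 lower in Mn11 in regular and 4 and 14 in manganese medium. Hypoxia targets rose in 3 of 28 in neo, and 2 rose and 2 fell in Mn11, while 5 were higher and 14 lower in Mn11 in regular and 5 and 17 in manganese medium. Of 22 genes of the citric acid (TCA) cycle, 1 rose and 1 fell in neo and 2 rose in Mn11, with 4 higher and 8 lower in Mn11 in regular and 7 and 6 in manganese medium. Luminal epithelial markers rose in 2 and fell in 1 of 23 in neo, and 1 rose in Mn11, with 11 higher and 7 lower in Mn11 in regular and 8 and 3 in manganese medium. Of 23 mesenchymal transition markers, 2 rose in neo, and 1 rose and 2 fell in Mn11, while 8 were higher and 5 lower in Mn11 in regular and 7 and 5 in manganese medium. Stem cell markers rose in 2 and fell in 1 of 17 in neo, and 1 rose and 1 fell in Mn11, with 8 higher and 4 lower in Mn11 in either medium. Among markers of other cell types, 1 of 7 fibroblast markers was higher and 2 were lower in Mn11 in either medium, and none changed with manganese. Of 13 leukocyte markers, 3 were higher and 3 lower in Mn11 in regular and 2 and 5 in manganese medium, and 1 rose with manganese in each line. Of all 145 list tests 48 were called, and the median, mean and test direction differed in sign in 23, none of them called.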

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

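The counts of other splits of the arrays were planned as tests. The use of the planned fits with slide as a block, with quantile or median scaling and without single arrays as tests of the explanations below, the normexp fit and the tests of other cell types, diverged lines and effects alike in both lines were chosen only after the results were seen.

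Each value here was noted because the effect of manganese differed between Mn11 and neo. For 2193 genes it differed, and among 100 draws of the medium labels within each line, the real one included, 1 draw gave as many. The highest of the others gave 418 genes. Of the other draws 0 kept the media whole in both lines, so they put any real manganese effect into the spread, and they ignored the slides. They therefore speak only against no effect of manganese at all. Whether the effects differ between the lines cannot be decided by them. With slide as a block 162 genes differed. The comparisons of 3 arrays with 3 have too few splits (10) for a share under 0.05. Their real counts were 13621 and 14153 genes between the lines in regular and manganese medium, 2190 for manganese in neo and 1857 in Mn11, and the highest other counts were 0, 0, 0 and 5.

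The mean effect of manganese on 31 ATF4 targets was lower in Mn11 than in neo by a log2 difference of -1.27 (adjusted camera p = 1.57e-22, adjusted p = 0.259 with an estimated correlation), and within Mn11 all 3 manganese arrays lay below all 3 regular arrays. The tables argue against differences between slides as the whole cause of the fall in Mn11, since its mean was -0.92 with slide as a block. That value has only Mn11 3 on the side of regular medium. They also argue against the array Mn11_supp 2 alone, since the mean was -0.96 without that array. The interaction, by which the list was picked, is no separate test of an effect alike in both lines. For the list's mean per array it was -1.27 ± 0.12 (log2, SE). With slide as a block, a fit that rests on few arrays per slide, it was -1.11 ± 0.15. The list was picked by this difference and did not stand apart from other genes with an estimated correlation, so its size stays a hypothesis, and what it owes to SOD2 is open with 1 line of each status.

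SOD2 differed by 1.14 between the lines in its manganese effect, higher in 3 of 3 Mn11_supp arrays than in any Mn11 array. The tables argue against slide differences (1.08 in Mn11 with slide as a block) and array scaling (0.83 as the lowest of 3 other scalings) as the cause of the rise in Mn11. The interaction, by which SOD2 was flagged, is no separate test of an effect alike in both lines. It was 1.14 ± 0.19 (log2, SE) and 1.36 ± 0.25 with slide as a block. Its call ended in that fit (adjusted p = 0.0569), which rests on few arrays per slide. The unadjusted p rose from 0.00011 to 0.000491, and since fewer genes had small p-values the largest one called fell from 0.00442 to 0.000323, so both changes were needed to end the call.

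The broad difference between the lines is the background to these interactions. In regular medium 7222 genes were still called with slide as a block, which argues against slides as the whole cause. Of 20 tested fibroblast and leukocyte markers 4 were higher and 5 lower in Mn11, which argues against fibroblasts or leukocytes in the Mn11 cultures as the cause. These markers cannot show cells of other types, such as another epithelial line, so that question stays open. Divergence of the lines apart from SOD2 cannot be told apart from an effect of SOD2, since there was 1 line of each status.

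Among single genes, the manganese effect was higher in Mn11 than in neo for FOLH1 (3.21), KLK8 (2.71), ELOVL2 (2.31), DPY19L2 (2.27), MUC1 (2.05) and SPINK4 (1.90), on the log2 scale. It was lower for CAMP (-3.64), NUPR1 (-3.41), CYP1A1 (-3.32), VLDLR-AS1 (-3.05), SLC7A11 (-2.91) and SLC43A1 (-2.81). The mean interaction of the other called lists was -0.41 for metallothioneins and zinc efflux, 0.26 for OXPHOS complex I, 0.25 for OXPHOS complexes II to V, 0.16 for endoplasmic reticulum chaperones, 0.25 for cholesterol synthesis, -0.47 for matrix and matrix proteases, 0.27 for the cell cycle, 0.15 for p53 targets and -0.41 for the interferon response. With an estimated correlation none of these lists stayed called (adjusted p between 0.259 and 0.575), and with slide as a block metallothioneins and zinc efflux and p53 targets did not (adjusted p = 0.0559 each).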

How the results depend on the processing

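Normexp correction was chosen only after the data were seen, and the other alternatives were planned. No called list and no named gene turned direction under any alternative run. Leaving out arrays aside, 2472 values of named genes kept their side of the threshold, 181 lost and 44 gained a call, and of the values of called lists 498 kept and 78 lost it, 44 of these with an estimated correlation. Of the counts, overlaps and SOD2 differences that answer a comparison, 242 values were kept. Those that were not follow, by alternative, and except where stated the cause was not tested.

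Slide as a fixed block gave 7222 genes that differed between the lines in regular and 6695 in manganese medium, 150 changed with manganese in neo (92 by at least 2-fold), 505 in Mn11, and 162 differed in the interaction (156 by at least 2-fold). The lines' calls then overlapped between media in 4600 genes and the manganese calls between lines in 11, and the SOD2 interaction was 1.36 (adjusted p = 0.0569, between 0.00053 and 0.0569 over the alternatives). This fit leaves fewer degrees of freedom and, for manganese, 1 array against 3 within a slide. With only the 6 Mn11 arrays 153 genes changed with manganese, 104 by at least 2-fold, and SOD2 differed by 0.85 without a call.

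Centring on the median gave 1304 genes for manganese in neo, 1033 in Mn11, 1228 for the interaction and an overlap of the manganese calls of 70. Of the calls for manganese 48.8% were then higher in neo, against 56.8%, and 34.9% in Mn11, against 42.5%, the largest falls of that share under the other scalings. Without a filter on dim probes 1234 genes changed in Mn11, 1451 differed in the interaction and the overlap was 92. A robust trended variance gave an overlap of 262. Normexp correction gave 2368 genes of at least 2-fold between the lines in each medium, 78 for manganese in neo, 102 in Mn11 and 274 for the interaction.

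With an estimated correlation 0 lists were called between the lines in regular medium (7 with the preset correlation) and 0 in manganese medium (5), 2 for manganese in neo (13), 2 in Mn11 (13) and 0 for the interaction (10). Fry, which does not compare a list with other genes, called 20 and 19 lists between the lines in regular and manganese medium and 16 for the interaction.

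Leaving out each array in turn left 2 arrays in its group. Genes changed ranged from 12301 to 13762 between the lines in regular medium, 12308 to 14406 in manganese medium, 922 (without neo_supp 2) to 2382 for manganese in neo, 689 (without Mn11 2) to 2473 in Mn11 and 1087 (without neo_supp 2) to 2782 for the interaction. Genes of at least 2-fold ranged, in the same order, from 4327 to 4528, 4716 to 5060, 187 to 336, 184 (without Mn11 2) to 517 (without Mn11 3) and 450 to 1180 (without Mn11 3). The SOD2 difference ranged from 2.99 to 3.29, 4.28 to 4.34, -0.33 to -0.26, 0.73 to 1.02 and 1.03 to 1.32, and called lists from 6 to 9, 5 to 5, 12 to 14, 11 to 14 and 8 to 11. SOD2 in neo passed the test only without Mn11 1 (adjusted p = 0.04). The overlap of calls ranged from 9114 to 9778 between media and from 73 (without neo 3) to 252 (without Mn11 1) between lines. Of the values of named genes 201 lost and 15 gained a call, and of lists 19 lost it.

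Replicate numbers were not taken to pair the cultures, since the labels do not say that a number marks a shared batch and not every pair's residuals correlated above 0.1. In 18 pairs of arrays with one number the correlation of residuals across genes was between -0.14 and 0.33 with a median of 0.03, and the closest array bore the same number in 12 of 36 trials. Within a line all 6 such pairs were positive (0.04 to 0.33), 3 of them above 0.1, and 9 of 12 pairs with different numbers were negative, so a weak pairing within lines is not excluded. With replicate as a block 13503 and 14039 genes differed between the lines, 1802 and 1574 changed with manganese in neo and Mn11, and 1756 differed in the interaction. No list was tested for every probe by itself, the 6-array fits or the random slide block, which camera does not take, and the interaction has no 6-array fit. The planned normexp correction of the mean signal was not run, since the files have no such column. Folds of genes below background in a group are lower bounds.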

Other observations

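The groups tested here, MHC class II genes and aryl hydrocarbon receptor targets, were chosen after the named genes were seen.

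MHC class II genes present antigen to helper T cells. With manganese in neo, of 11 tested members other than HLA-DRA and HLA-DRB5, 6 rose and none fell (camera p = 4.73e-06, and 0.0128 with an estimated correlation). CIITA, the regulator of class II transcription, rose 2.15-fold (log2 1.10 ± 0.14, adjusted p = 0.00201) and the invariant chain CD74 1.88-fold (adjusted p = 0.0202). HLA-DPA1, HLA-DMB, HLA-DRB1 and HLA-DMA rose 2.37-fold, 1.94-fold, 1.47-fold and 1.29-fold (adjusted p = 0.016, 0.00427, 0.0227 and 0.0248). In the interaction 4 of the 11 were lower in Mn11 than in neo (camera p = 0.0129, and 0.122 with an estimated correlation), namely CIITA (-1.06), CD74 (-1.55), HLA-DMB (-1.22) and HLA-DPA1 (-1.98). With slide as a block the group's mean was 0.50 in neo, against 0.54, with a camera p of 6.94e-05, but none of the 11 was called. CIITA was then at 0.96 (adjusted p = 0.0666) and HLA-DMB at 1.06 (adjusted p = 0.059). In the interaction only HLA-DPA1 stayed called in that fit (-2.30, adjusted p = 0.0331), with a camera p of 0.151 for the group.

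HLA-DRA and HLA-DRB5 rose with manganese in Mn11. Their log2 means were also higher in neo_supp (-3.70 and -2.20) than in neo (-4.84 and -3.19). A candidate explanation is that class II genes rise together. Of the 11 others 2 rose in Mn11, HLA-DRB1 by 2.19-fold (adjusted p = 0.00117) and HLA-DQB1 by 1.23-fold (adjusted p = 0.0371). The camera p was 0.532 over the 11 genes, so the group as a whole did not pass the test, and the group's mean was -0.00. HLA-DPA1 (-0.73), CD74 (-0.64) and HLA-DMB (-0.26) had negative differences that did not pass it, and CIITA stood at 0.05 (adjusted p = 0.86). With slide as a block 1 of the 11 rose, HLA-DRB1 (1.40, adjusted p = 0.00423), and 1 fell, HLA-DPA1 (-1.33, adjusted p = 0.0345). HLA-DRB1 shares sequence with HLA-DRB5, and these counts do not settle the explanation.

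CYP1A1, CYP1B1 and UGT1A6, which rose with manganese in neo, are known targets of the aryl hydrocarbon receptor, a sensor of foreign compounds. A candidate explanation is that targets of this receptor rise together. Of 7 other tested targets 2 rose in neo, TIPARP by 1.42-fold (adjusted p = 0.0494) and NFE2L2 by 1.37-fold (adjusted p = 0.0382), and the group's camera p was 0.0499, and 0.154 with an estimated correlation. With slide as a block neither was called and the camera p was 0.075. In the interaction none of the 7 was higher and 1 was lower, SLC7A5 at -1.27 (adjusted p = 0.001), a gene also among the ATF4 targets that stayed called with slide as a block (-1.14, adjusted p = 0.0399). The group's mean interaction was -0.21 with a camera p of 0.118, and -0.44 with a camera p of 0.0129 with slide as a block, lower in Mn11 than in neo. These counts do not settle the explanation.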
